A study of Mus musculus with 6 samples.

How the data were processed

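RNA from medulloblastoma and from granule neuron precursors was hybridised to 1-colour Agilent arrays of a mouse lncRNA design, 3 arrays per group. Per the labels' protocols, rRNA was removed and RNA was amplified and labelled along the transcripts by random priming. Per the file headers, the authors' scanner files hold spot intensity values made with Feature Extraction 11.0.1.1. These are the processed signal, the median signal and background, and flags for each spot. The authors also deposited a normalized table and a series matrix, which the values show to be on a log2 scale with nearly equal distributions: the median log2 value was 5.50 in each column of both, and the 75th percentile in the table was 8.08. The method behind that table is not given in the sources used here. Each column ranked closest to its own array's scanner values, with slopes of 0.986 to 1.01 on log2 scanner signal, which settles the log2 scale and the direction. Since median and 75th percentile were both nearly equal across columns, the distributions had been equalised and not only shifted; the step that did so, and its centre, stay unknown. The series matrix equalled the normalized table at each of its 60804 probes.

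From the scanner files, log2 of the processed signal was taken, spots flagged as non-uniform or population outliers (58 to 187 per array) were set missing, spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. No non-control spot was saturated. Of 61500 spots that the files do not mark as controls, 300 belong to 15 probes named as negatives, which were kept out of tests. Between 2.67% and 8.00% of negative spots were well above background. Probes tested were those well above background on every array of at least 1 group.

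Arrays were compared before averaging. The SD per array of a pair's difference (a median absolute deviation scaled to an SD, over tested probes with mean log2 signal above 8) was set against the plain and the equally scaled SD of 20 repeated spots of 13 bright probes within an array. A pair within a group counted as 1 sample where its ratio to the plain spot SD was below 1.5; the ratio to the scaled spot SD puts the same pairs below 1.5. This limit was set after the array similarities had been seen, and before counts of changed probes were computed. It averaged precursor replicates 1 and 4 and tumour replicates 1 and 2. The design fixed before the data were examined names 6 arrays as separate samples, 3 per group, and so differs from the 4-sample fit given first in the results. Both fits are given for the counts of changed probes. The first fits tried, before the alternatives were scripted, were these 2 designs under the 75th percentile, median and quantile scalings, the 4-sample fit with a trended and robust variance, and the other splits of the 4 samples.

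Tumours were compared with precursors with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment, with the package data.table (version 1.17.8) for reading files. Differences are tumour minus precursor, with SDs over 2 samples per group. The scripts were tested on simulated data for this comparison, with 200 of 40887 probes changed in each of 10 runs. Simulated probes varied independently of each other, and all had the same noise between repeats, 0.05 log2 units. The 4-sample fit recovered 0 of 670 probes changed 2-fold, 0.448% of those changed 8-fold and 59.1% of those changed 64-fold. The 6-array fit recovered 36.1%, 90.7% and 98.5%, with 11999 false calls over the runs against 31 for the 4-sample fit.

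The scanner files pair only 15 probes with RefSeq accessions, and all 15 matched a symbol in a RefSeq table of assembly GRCm38.p6 without versions. Other probes have catalogue or lincRNA names. Of the 31 gene lists fixed before the data were examined, only 2 members, B2m and Gapdh, had a named probe, so no list could be tested and no test of coding against noncoding probes was run. The rule for named genes gave way, as fixed for probes without gene names, to at most 2 probe numbers in each direction, plus up to 4 noncoding probes in each direction by name. As no probe passed with 4 samples, the rule's threshold was applied to the 6-array fit, with all tumour values on one side of all precursor values and signal well above background on all 6 arrays. The 15 control genes are given whole, a choice made after their values were seen. Alternatives covered scaling, background correction, the authors' tables, filters, flags, variance models, array weights, slide and left-out replicates. The normexp alternative was planned on mean signals and was run on median signals with an offset of 50.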

Results

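Gene expression was measured by 1-colour microarray in medulloblastoma, a tumour of the cerebellum, and in the cerebellar granule neuron precursors from which the Sonic Hedgehog form of this tumour arises. The mice carried a transgene for a constitutively active Smoothened, the signalling protein of the Hedgehog pathway, in cerebellar granule cells. Tumour cells came from mice 4 months old and precursors from mice of the same strain 4 to 6 days old. Tumour and age thus differ together, and their effects cannot be told apart in any comparison below. There were 6 arrays, 3 of tumours (replicates 1 and 2, and a replicate titled MB915) and 3 of precursors (replicates 1, 3 and 4). Each array held 60930 different probes apart from control spots. Between 40571 probes (tumour replicate 1) and 43902 probes (tumour replicate 2) were well above background on an array. The 75th percentile of signal ran from 213 in tumour replicate 1 to 321 in tumour replicate MB915. The small number of arrays limits the precision of every value.

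Precursor replicates 1 and 4 were nearly identical, as were tumour replicates 1 and 2. Over 15348 bright probes, the SD per array of the difference was 0.041 log2 units between precursor replicates 1 and 4 and 0.060 between tumour replicates 1 and 2. Repeated spots of a single probe within an array varied with an SD of 0.042 to 0.089. With the same robust measure for spots, the pair SD was 0.953 times the spot SD for the precursors and 1.24 times for the tumours, and with plain SDs on both sides these ratios were 0.880 and 1.01. The other pairs within a group had robust ratios from 8.29 to 14.3, and no bright probe differed by over 2-fold within either near-identical pair. The precursor pair thus differed by less than the noise between spots, and the tumour pair by about that noise or slightly more. The mean of each pair was counted as 1 sample, which leaves 2 samples per group. The study's design speaks of 3 cases of tumour cells paired with precursors and names no array as a repeat, so the count of 2 samples per group rests on the measured values alone. Nothing in the labels says whether the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

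**Figure D1:**
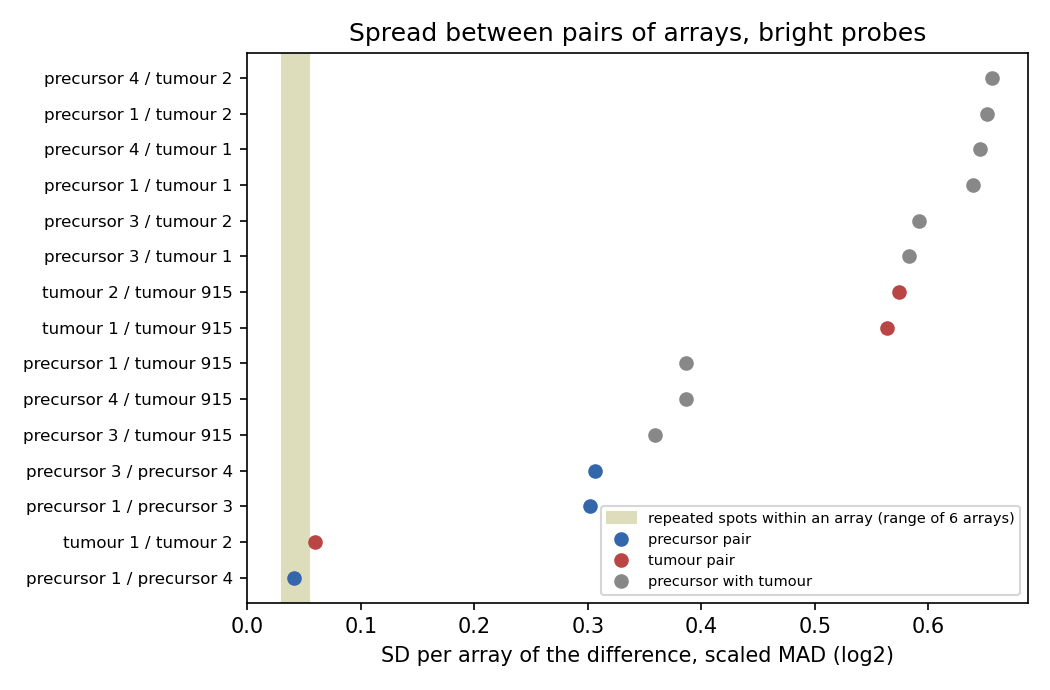
Spread between each pair of arrays, as the SD per array of the log2 difference over 15348 bright probes; each point is a pair, and both the points and the shaded band, the range of repeated spots within the 6 arrays (0.030 to 0.055), are SDs scaled from the median absolute deviation. Precursor replicates 1 and 4 (0.041) lie within the band and tumour replicates 1 and 2 (0.060) just above it, and all other pairs lie at 0.30 or above.

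The main comparison asked which transcripts differ between the tumours and the precursors. Rpl13a, a protein of the large ribosomal subunit, was 3.27-fold higher in the tumours, and B2m, the light chain of major histocompatibility complex class I molecules, was 2.05-fold higher. Neither passed the test. In limma, 0 of the 40887 probes tested passed a Benjamini-Hochberg adjusted p under 0.05, so 0 were higher, 0 were lower and 0 were changed at least 2-fold. At an unadjusted p under 0.05 there were 4585 probes, where 2044 would be expected by chance. The 6-array fit had 14628, or 35.8% of the probes, where 21.9% fell under 0.05 in simulated data with no changed probe and the same repeat structure. The unadjusted count of the 4-sample fit was not stable. It fell with either precursor sample left out and rose with either tumour sample left out. Such fits leave a group without replication, so they cannot show how far the excess over chance depends on single samples. With the 6 arrays taken as separate samples, as the design fixed beforehand was worded, limma called 5298 probes, 2872 higher and 2426 lower in the tumours, of which 3838 changed at least 2-fold. The 6-array count treats each near-identical pair as 2 independent samples. In those simulated data the 6-array fit made a median of 995 calls over 10 runs among 40887 probes, and the 4-sample fit made 0. The simulated probes varied independently, so variation that probes share between samples was not modelled. The 995 calls and the 21.9% therefore show that the repeat pairs give false calls, and not how many of the 5298 are real.

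The split between directions in the 6-array fit depended on the scaling. A median shift gave 2039 higher and 2939 lower, and quantile normalization gave 2340 higher and 2692 lower. The median difference over the tested probes of the 4-sample fit was 0.08 log2 units, against -0.07 after a median shift. Each of the 2 slides held arrays of both groups. On slide 1, which held 1 array of each of the 4 samples, limma called 0 probes, with 4572 at an unadjusted p under 0.05. Slide 2 held 1 array per group, precursor replicate 4 and tumour replicate 1, and allows no test. There the tumour array was at least 2-fold higher at 6635 probes and at least 2-fold lower at 5872. Both arrays are members of the near-identical pairs whose other members lay on slide 1. Like values on the 2 slides are therefore no independent replication. With the slide as a block and the repeat pairs as a random block, 4 probes passed, and with the slide as a block on 6 separate arrays 1864 passed.

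Probes were also counted where every tumour sample lay at least 2-fold above, or at least 2-fold below, every precursor sample. There were 1027 such probes higher in the tumours and 1066 lower, of which 274 and 254 were apart by at least 4-fold. The other 2 splits of the 4 samples gave 333 and 412 probes in all, against 2093. Of the 40887 probes tested, 36087 were well above background on all 6 arrays. The rest entered through the detection of 1 group, which favours the real split in this count. Well above background on all 3 tumour arrays and on no precursor array were 389 probes, and 584 showed the opposite. Most probes carry only a catalogue number that the files used here do not pair with a gene, so 2 in each direction are given by number. They had the largest 4-sample differences among catalogue probes that passed in the 6-array fit, were well above background on all 6 arrays and did not overlap between the groups. ASMM10P037616 was 195-fold higher in the tumours, at -4.00 ± 0.08 in precursors and 3.61 ± 0.48 in tumours (log2 relative to the 75th percentile, SD, n = 2 samples per group), with a limma adjusted p of 0.0948. It passed in limma with the slide as a block and repeat pairs as a random block (adjusted p 0.0150). With repeat pairs as a random block and no slide term, limma passed each of the 4 numbered probes, with adjusted p of 0.00168 for ASMM10P037616, 0.0366 for ASMM10P002419, 0.0165 for ASMM10P026803 and 0.0331 for ASMM10P045724. The 4 probes were chosen by the 6-array fit on the same arrays, so these block fits give them no independent support. Both block fits take 1 correlation within pairs for all probes, 0.963 without the slide term and 0.971 with it. ASMM10P002419 was 111-fold higher (limma adjusted p 0.199). ASMM10P026803 was 112-fold lower in the tumours, at 5.19 ± 1.28 in precursors and -1.62 ± 0.65 in tumours, and ASMM10P045724 was 102-fold lower (limma adjusted p 0.162 and 0.188). Their adjusted p in the 6-array limma fit ran from 0.00038 for ASMM10P037616 to 0.0102 for ASMM10P045724. With normexp on median signals, a setting that changes the signal type and the background correction and adds an offset of 50, these differences were smaller. With it and the 75th percentile, the log2 difference of ASMM10P037616 fell from 7.61 to 5.54 and that of ASMM10P002419 from 6.80 to 5.18. For ASMM10P026803 it was -6.01 in place of -6.81, and for ASMM10P045724 -5.49 in place of -6.67. Single samples moved them as well: ASMM10P002419 stood at 8.12 without tumour replicate MB915 and at 5.47 with tumour replicates 1 and 2 left out. ASMM10P045724 stood at -5.24 without precursor replicate 3 and at -8.11 with precursor replicates 1 and 4 left out. ASMM10P026803 stood at -7.72 and -5.90 in the same settings. On slide 1 the difference for ASMM10P037616 was 7.61 log2 units and on slide 2, whose arrays nearly equal arrays of slide 1, it was 7.21. For ASMM10P002419 these values were 6.81 and 8.89, for ASMM10P026803 -6.82 and -7.25, and for ASMM10P045724 -6.68 and -5.33.

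A set of 15 genes, called control genes here, could be named through their accessions, and each was well above background on all 6 arrays. Some were dim: Ldhal6b stood at -2.06 in precursors, against 9.16 for Ppia. With limma 0 of the 15 passed, over all probes or adjusted over the list alone, and 1 was under 0.05 unadjusted. Rpl13a stood at 4.78 ± 0.15 in precursors and 6.49 ± 0.43 in tumours (SD, n = 2 samples per group), a difference of 1.71 log2 units (SE 0.35, limma adjusted p 0.262). It was the 1 gene of the set to pass in the 6-array fit (limma adjusted p 0.00899). Its difference was 1.72 on slide 1 and 1.89 on slide 2, whose arrays nearly equal arrays of slide 1 and so add no replication. Both tumour samples lay above both precursor samples for Rpl13a. B2m stood at 6.04 ± 0.73 in precursors and 7.08 ± 0.30 in tumours, a difference of 1.04 (SE 0.46, limma adjusted p 0.502), with 1.06 on slide 1 and 1.72 on slide 2. The B2m difference was 1.55 without precursor replicate 3 and 0.52 with precursor replicates 1 and 4 left out. The difference for Nono, an RNA-binding protein, was 0.33, and its samples did not overlap either, by a gap of 0.035. Nono stood at 0.12 without MB915 and at 0.53 with tumour replicates 1 and 2 left out. By chance, samples of 2 groups of 2 fail to overlap for 33.3% of genes. The other 12 genes overlapped between the groups, and the sign of 10 of them turned when samples were left out or the arrays counted or scaled otherwise. Their differences ran from 0.29 for Gapdh, the glycolytic enzyme, through 0.21 for Ppia, the peptidyl-prolyl isomerase, to -0.36 for Tfrc, the transferrin receptor. Without MB915 Gapdh stood at 0.60 and Ppia at 0.40. With tumour replicates 1 and 2 left out they stood at -0.012 and 0.0083. Tbp, the TATA-box binding protein, stood at 2.88 in the mean of tumour replicates 1 and 2 and at 4.26 in tumour replicate MB915, on either side of the precursor mean of 3.72. Gusb and Ldhal6b changed sign between scalings or background corrections, and Actb and Hsp90ab1 between scalings in the 6-array fit, so no direction is given for these genes. The control probes for Pgk1, a glycolytic enzyme, moved in opposite directions by the end they are named for: the probe named 3 was 0.40 log2 units higher in the tumours and the probe named 5 was lower, at -1.06.

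**Figure D2:**
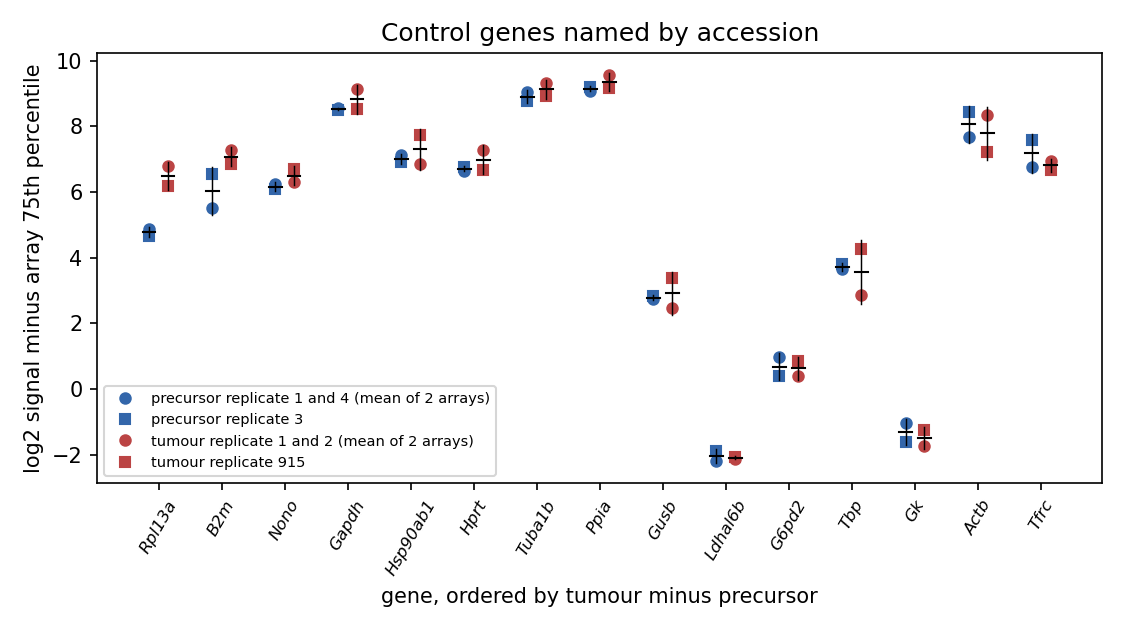
Log2 signal relative to the array's 75th percentile for 15 control genes in each of the 4 samples, precursors in blue and tumours in red; black horizontal lines are group means and vertical lines are 1 SD (n = 2 samples per group). Rpl13a has the widest gap between the groups (4.78 in precursors, 6.49 in tumours), and no gene passed the limma test with 4 samples.

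Probes whose names mark them as long intergenic noncoding RNAs numbered 1836, of which 643 were tested. They were detected less widely than the catalogue probes: 28.6% were well above background on all 6 arrays, against 60.2% of catalogue probes and 0 of the 15 probes named as negatives. They include 876 pairs whose names differ only in the sign. If the signs stand for strands, a pair can hold a probe with no transcript to read. These shares therefore compare probes and not transcripts. None passed in limma with 4 samples, with 42 at an unadjusted p under 0.05. In the 6-array fit 50 passed, 39 higher and 11 lower, which is 7.78% of those tested, against 13.0% of catalogue probes. Every tumour sample lay at least 2-fold above every precursor sample at 17 lincRNA probes and at least 2-fold below at 5. Together these were 3.42% of those tested, against 5.15% of catalogue probes. The median difference with 4 samples was 0.17 for lincRNA probes and 0.08 for catalogue probes. The directions within this class were not counted under other scalings, so no direction is given for lincRNAs as a group. Named by the rule fixed beforehand, applied to the 6-array fit, the probes with the largest positive differences were mouselincRNA0392+_P1 (5.45-fold), mouselincRNA0413+_P1 (5.03-fold), humanlincRNA1543-_P1 (5.01-fold) and mouselincRNA1235-_P1 (4.34-fold). With 4 samples their limma adjusted p ran from 0.338 for mouselincRNA0413+_P1 to 0.426 for mouselincRNA1235-_P1. In each of them the difference from the precursors was larger in tumour replicates 1 and 2 than in MB915, as for mouselincRNA0392+_P1 with 3.27 against 1.62 log2 units. With normexp and the 75th percentile the log2 difference was 1.06 in place of 2.45 for mouselincRNA0392+_P1, 1.35 in place of 2.33 for mouselincRNA0413+_P1, 1.40 in place of 2.12 for mouselincRNA1235-_P1 and 1.78 in place of 2.33 for humanlincRNA1543-_P1, which then had the largest of the 4. With tumour replicates 1 and 2 left out, these 4 differences ran from 1.09 to 1.62, and without MB915 from 3.13 to 3.27. The probes lower in the tumours that met the rule were mouselincRNA0435+_P1 (1.88-fold), humanlincRNA1518-_P1 (1.73-fold) and humanlincRNA0318+_P1 (1.69-fold), with limma adjusted p of 0.423, 0.447 and 0.482 with 4 samples. With normexp and the 75th percentile the log2 difference of mouselincRNA0435+_P1 was -0.55 in place of -0.91, that of humanlincRNA1518-_P1 -0.56 in place of -0.79 and that of humanlincRNA0318+_P1 -0.87 in place of -0.76. For mouselincRNA0435+_P1 it was -1.15 without precursor replicate 3 and -0.67 with precursor replicates 1 and 4 left out. On slide 1 the 7 differences ran from 2.39 for mouselincRNA0392+_P1 to -0.93 for mouselincRNA0435+_P1, and on slide 2 from 3.41 for mouselincRNA0413+_P1 to -1.15 for humanlincRNA0318+_P1. The arrays of slide 2 nearly equal arrays of slide 1, so the slides are not independent. None of the 7 passed with the slide as a block on 6 separate arrays (limma adjusted p from 0.054 to 0.085). Nor did any with repeat pairs as a random block and no slide term (limma adjusted p from 0.153 to 0.374).

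The 2 tumour samples differed from each other about as much as from the precursors. The root mean square difference over tested probes was 1.02 log2 units between the tumour samples and 0.72 between the precursor samples. Tumour replicate MB915 lay 0.977 from precursor replicate 3 and 0.997 from the mean of precursor replicates 1 and 4. The mean of tumour replicates 1 and 2 lay 1.16 and 1.21 from the same samples. At least 2-fold apart were 9644 probes between the tumour samples, 23.7% of those tested, and 4757 between the precursor samples. The log2 difference between the Pgk1 probes named 3 and 5 also set the samples apart, at 4.05 to 4.33 on the precursor arrays, 5.11 in MB915 and 6.21 and 6.22 in tumour replicates 1 and 2. The mouse Gapdh control probes placed MB915 otherwise. Their difference was 0.28 in MB915, below the 0.64 to 0.70 of the precursor arrays, and 1.18 to 1.25 in tumour replicates 1 and 2. Differences of the tumour samples, each taken from a different precursor sample so that no control was shared, correlated across probes with Pearson's r of 0.33 in one pairing and 0.38 in the other. Probes are not independent replicates. In the first pairing 3883 probes were at least 2-fold apart in both differences, of which 76.1% went the same way. Probes tested through the detection of 1 group favour such agreement and a positive r.

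**Figure D3:**
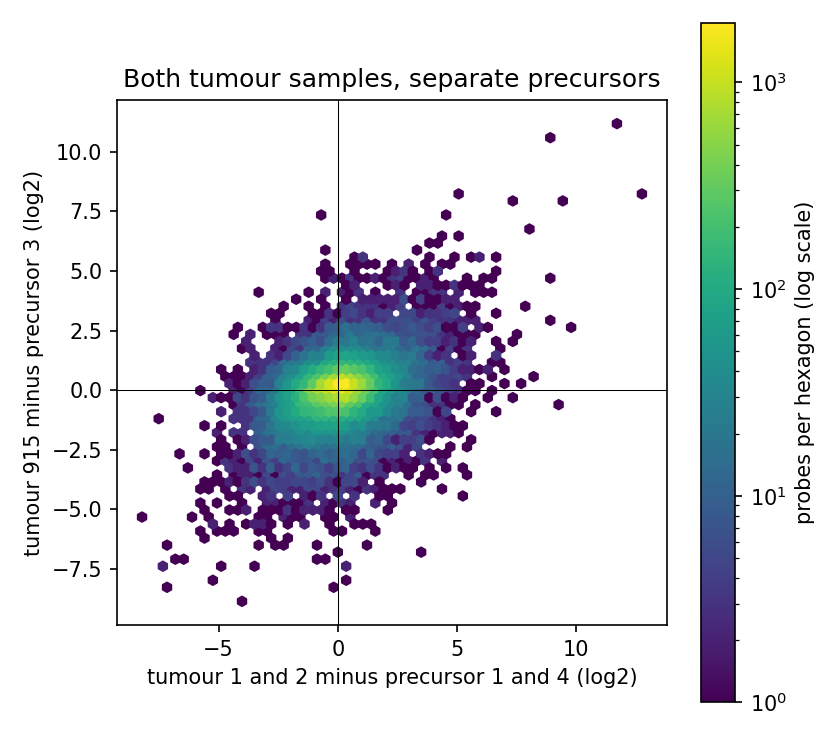
Log2 difference of tumour replicates 1 and 2 from precursor replicates 1 and 4 (horizontal axis) against that of tumour replicate MB915 from precursor replicate 3 (vertical axis); colour gives the number of tested probes per hexagon on a log scale. The differences of the tumour samples are correlated across probes (r = 0.33) with a wide scatter.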

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

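Control spots, which enter no comparison, were looked at after their values were seen. Of 20 control spot names well above background on all 3 tumour arrays, 7 had both tumour samples above both precursor samples, where chance gives 16.7%. Many of the names are human, mouse or rat versions of GAPDH and PGK1 probes. The 20 are therefore not independent, and setting 7 against this share is no test. The tumour minus precursor differences in log2 units were 0.37 for Human-GAPDH_3, 0.46 for Human-PGK1_3, 0.33 for Mouse-GAPDH_5, 0.40 for Mouse-PGK1_3 and 0.50 for Rat-GAPDH_3. ERCC-00012_90 and ERCC-00104_60, probes named for spike-ins, differed by 0.27 and 0.36. Others named so, such as ERCC-00043_129 and ERCC-00171_229, were well above background on 0 arrays. Whether these signals come from added spike-ins is thus not known. Most spots well above background on 0 arrays also stood higher in the tumours, as ETG02_36680 at 0.28, and a few lower, as DCP_1_0 at -0.42. The log2 75th percentile subtracted was 7.73 and 7.84 in tumour replicates 1 and 2, against 8.16 to 8.25 on the precursor arrays. This raises spots at the floor on those tumour arrays. In MB915 it was 8.33, which does not. The difference of ERCC-00012_90 is about the size of this shift at the floor. On the lower side 4 of the 20 names stood apart, ERCC-00062_278 at -0.48 and the 3 PGK1 probes named 5 at -1.06 (mouse), -1.08 (human) and -1.08 (rat). No biological explanation was tested for these values.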

How the results depend on the processing

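The design fixed before the data were examined counts 6 arrays as separate samples; averaging the near-identical pairs was chosen after the arrays were compared. So were the 6-array fits with another scaling or a block, repeat pairs as a random block, slide 1 alone, and a pair of replicates left out. With pairs averaged, the counts of 0 probes changed, higher, lower and changed at least 2-fold held under 10 of the planned settings that keep every array. A median shift, or array weights, gave 1 probe changed, 1 higher and 1 at least 2-fold; the cause was not tested. With slide as a block and repeat pairs as a random block these counts were 4, 3 and 4, with 1 lower. Leaving out 1 replicate at a time gave 0 to 1 changed, 0 to 1 higher, 0 lower and 0 to 1 at least 2-fold; without tumour replicate 2 it was 1. Without precursor replicate 3 or tumour replicate MB915 a group has 1 sample, assumed to vary like the other group. Limits of 1.5-fold and 4-fold, and treat against 1.2-fold, can only give 0 where no probe passes, and test nothing here.

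Counting 6 arrays as separate samples gave 5298 changed (2872 higher, 2426 lower, 3838 at least 2-fold). With a median shift it gave 4978 (2039, 2939 and 3815), with quantile normalization 5032 (2340, 2692 and 3736), and with slide as a block 1864 (932, 932 and 1819). With repeat pairs as a random block, 212 changed (125 higher, 87 lower, 212 at least 2-fold). That fit takes 1 correlation within pairs (0.963) for all probes. The cause of the differences between these counts was not tested. No paired analysis was possible because the groups share only the replicate number 1, although the design speaks of 3 pairs.

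Rpl13a, B2m, Nono, Tuba1b, Ppia and the 11 probes named by number or lincRNA name kept their direction in each setting that gave them a value, but not their size: ASMM10P037616 ranged from 5.43 to 7.95 and mouselincRNA0392+_P1 from 0.96 to 3.27. Rpl13a ranged from 1.40 to 2.02, with adjusted p from 0.00589 to 0.820. Sign changes were found for control genes that did not pass in any setting, and their cause was not tested. Gusb was -0.015 with a median shift, -0.33 without tumour replicate MB915, and with 6 separate arrays -0.0051 (also with slide as a block), -0.19 with a median shift and -0.034 with quantile normalization. Ldhal6b was 0.047 with normexp and the 75th percentile and, with 1 replicate left out, from -0.076 to 0.11 (without precursor replicate 3). Actb, at -0.30 without tumour replicate 2, was 0.12 without precursor replicate 3, 0.30 without tumour replicate MB915 and 0.050 with 6 separate arrays, with or without slide as a block. With 1 replicate left out, Tfrc ran from -0.37 to 0.054 (without precursor replicate 3); its lowest value was -0.78 with precursor replicates 1 and 4 left out. Hsp90ab1 was -0.15 without tumour replicate MB915, and with 6 separate arrays -0.072 with a median shift and -0.12 with quantile normalization. With precursor replicates 1 and 4 left out G6pd2 was 0.24 and Gk 0.10. With tumour replicates 1 and 2 left out Gapdh was -0.012, Hprt -0.041, G6pd2 0.18, Tbp 0.54 and Gk 0.060. Gene list alternatives and the split of coding and noncoding probes by brightness were not run. Signal over background limits the lincRNA probes, of which 28.6% were well above background on all 6 arrays.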

Other observations

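The test of the slide behind tumour replicate MB915, the count for other samples set beside the mixture test, and the limit of the strand test to pairs with both probes tested were chosen after the results were seen; the other tests below were written before theirs, except that the 6-array count for the real grouping was already known.

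Probes for Pgk1 of the mouse and human designs differed by the end they are named for; Rat-PGK1_3 was well above background on 2 arrays only. The probes named 5 were lower in the tumours by log2 differences of -1.06 (mouse), -1.08 (human) and -1.08 (rat), while Mouse-PGK1_3 and Human-PGK1_3 were higher. The log2 difference between Mouse-PGK1_3 and Mouse-PGK1_5 was 4.05 to 4.33 on the precursor arrays, 5.11 in tumour replicate MB915 and 6.21 and 6.22 in tumour replicates 1 and 2. For Mouse-GAPDH the same difference was 0.64 to 0.70 on the precursor arrays, 0.28 in tumour replicate MB915 and 1.18 to 1.25 in the others.

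Tumour replicate MB915 lay closer to the precursors than to the other tumour arrays. A precursor sample carrying a tumour label was predicted to have differences unrelated to those of the other tumour sample, and the lower of the correlations across probes was 0.33. Probes tested through the detection of 1 group favour a positive r. An unusual precursor sample could also differ in the same direction as the tumours, so this r cannot exclude a wrong label. The slide is argued against by tumour replicate 2, whose difference SD from replicate MB915 on its own slide was 9.60 times that from replicate 1 on the other slide. A mixture of the other tumours' RNA with precursor RNA would lie between its parts, and 430 probes in replicate MB915 stood at least 4-fold outside the range of the other samples. The bound set beforehand compared this count with repeat-pair noise, which was the wrong measure: precursor replicate 3 put 185 probes as far outside the rest, the mean of precursor replicates 1 and 4 put 243 and the mean of tumour replicates 1 and 2 put 888, so a mixture stays open. A difference in RNA integrity also stays open for this pattern and for the tumour counts. The Pgk1 end difference moves with both, at 5.11 in MB915, between the precursors and the other tumours. The Gapdh end difference goes the other way for MB915, at 0.28 against 0.64 to 0.70 on the precursor arrays. A mixture with cells of another kind and a difference between tumours of separate animals stay open too, both untested.

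The near-identical pairs lay on different slides. If the slide set what difference remained within them, the slide 2 minus slide 1 differences of the pairs would correlate across bright probes, and r was 0.049. The pairs may be repeat hybridisations of single RNA preparations, which the labels do not state; counting them as separate samples moved the number of changed probes from 0 to 5298.

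With 6 arrays as separate samples, 1 of 10 splits, the real one, gave as many changed probes, 5298 against at most 0 in the others. Of the 9 other splits 8 put the members of at least 1 near-identical pair on opposite sides, and the 1 that keeps both pairs whole gave 0. With 4 samples, 1 of 3 splits, again the real one, gave as many probes at least 2-fold apart, 2093 against at most 412. In both counts, probes tested through the detection of 1 group favour the real split. Neither design can give a share under 0.05.

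Of 876 pairs of lincRNA probes whose names differ only in the sign, both members were tested in 110, where 106 would be if detection were independent. If the signs stand for strands, labelling that loses the strand would make the signals of a pair correlate with a rho over 0.5. The Spearman rho of mean signal was 0.056 over all pairs (95% bootstrap interval to 0.12), and 0.13 over pairs with both members tested (interval from -0.057 to 0.34). Members near background can hold rho low whatever the labelling, so the rho over all pairs cannot decide. Over pairs with both members tested the interval stays below 0.5. This argues against a full loss of strand only if both members read the same transcript, which is not known. A partial loss stays open. Over those 110 pairs the rho of the tumour minus precursor differences was 0.055.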
